A study of Homo sapiens with 2 samples.

How the data were processed

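The series compared FaDu cells transfected with an EpCAM siRNA and FaDu cells transfected with a control siRNA, 1 array each. Both siRNAs were given at 100 nM, and Cy3-labelled cRNA was made from 500 ng of total RNA, per the labels' protocols. The printed strands, taken here as the sense strands, are UGCCAGUGUACUUCAGUUG for EpCAM and UCGUCCGUAUCAUUUCAAU for the control, each of 19 bases, per the labels. Their positions in the genome were not analysed here, and no genome sequence was used.

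Each array held 45015 spots, of which 43376 were gene spots of 41000 distinct probes. The deposited intensities were extracted with Agilent Feature Extraction 9.5.3.1 under the protocol GE1-v5_95_Feb07 from array design 014850 with the hg17 annotation, per the file headers. The intensity used here was the processed signal, which the authors' software had background-subtracted and corrected for spatial trends within each array, with a substitute value where a spot was not significantly above background, per the file headers. No normalization between arrays had been applied to it. Both arrays lay on the same slide and were read in the same scan, per the file headers, so neither separates the groups. The authors' deposited series table holds linear intensities that equal the processed signal times 1 constant per array, 1.03 for the EpCAM siRNA array and 1.20 for the control siRNA array. Both of its columns have a median of 147.2, it is not centred by gene, and it holds levels, not ratios, so it carries no direction. It served as an alternative. Other columns hold flags, such as well above background, saturated and outlier.

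Signals were taken to log2, and each array's 75th percentile over gene spots, 1474 and 1310 intensity units, was subtracted. Spots with a non-uniformity or population outlier flag on either array were left out, 89 gene spots being flagged on the EpCAM siRNA array and 96 on the control siRNA array. Spots of a probe were averaged. A probe counted as detected where at least 50% of its spots were well above background; 26334 probes were detected on both arrays, 440 only with EpCAM siRNA, 979 only with control siRNA and 13226 on neither, and 21 had no spot without a flag. Only 1 gene spot was saturated on each array. A gene's value was the mean over its probes detected on both arrays. Of 4794 genes with several such probes, 1399 had probes of opposite sign; among the genes at least 2-fold apart, 36 of 37 with several probes had the same sign in all.

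Gene symbols on the array were updated through an NCBI RefSeq gene table of GRCh38.p14 that was used for names alone. By accession 23434 probes were named, by current symbol 2317 and by a synonym held by a single gene 1044; 14205 probes stayed unnamed and entered no gene result. This gave 17520 named genes, of which 12664 were measured. Coordinates are those of the array files in hg17; exons and untranslated regions were not analysed here.

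With 1 array per group no test was possible and no p-value is given. Differences are EpCAM siRNA minus control siRNA. The error beside a difference combines the software's error of both signals, and for a gene with several probes it is their mean. The SD between replicate spots had a median of 0.13 for dim probes, 0.051 for probes of middle level and 0.036 for bright ones. For bright genes the software's error was nearly constant, at about 0.20, against that SD of 0.036. A count of such genes beyond the error is thus close to a count by a fixed size. Neither the error nor the SD covers biological spread. Genes at least 2-fold apart were counted by size. For 29 gene lists fixed before the data were examined, the median difference was set against 10000 random lists of the same size drawn within 20 bins of mean level, with 2000 random lists for each alternative setting. Lists outside the central 95% of the random lists were taken to stand apart, as a description of these arrays; lists with under 3 measured members got no median. Members of different lists overlap.

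Genes were named by a rule fixed before the data were examined: always-named genes, among them EPCAM and CCND1; the 12 largest differences in each direction among genes with a symbol, detected and unsaturated on both arrays, with all detected probes of the same sign; the 4 largest bounds in each direction among genes detected on 1 array; up to 4 members of each list with the largest absolute difference, or 6 for lists that stand apart; and each measured G1/S cyclin. Some genes that the rule selects are not reported here. All other genes named were chosen after their values were seen.

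The alternatives fixed beforehand were normexp background correction with an offset of 50 on the mean and local background signals, no background subtraction, scaling by the median of detected probes, quantile and loess normalization, scaling on spike-in probes, the authors' series table, no dim probe filter, brighter probes only, flagged spots kept, saturated probes left out, the brightest or the median probe of a gene, size thresholds of 1.5-fold and 3-fold, list means, and random lists not matched on level. After seeing the data, leaving out rows 190 to 351 and counting only genes at 1/8 of the 75th percentile or above were added. Median scaling, spike-in scaling and the authors' series table shift all genes of an array by 1 constant, and the saturated probes had no gene symbol. Apart from the random draws, these settings could not change a list's percentile, yet they are among the settings counted for each list below. Those rows are the longest run of neighbouring bins, among 20 bins of 27 rows, in which the share of dim spots at least 2-fold apart was over 2 times that of the median bin, a rule that was itself set after the excess had been seen. A search for siRNA seed sites in 3' untranslated regions had been planned only if transcript sequences were at hand; it was run on the 60-base probe sequences instead.

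The steps were tested on simulated data made from the control siRNA array, with 200 genes among 12664 changed by 1.5 on the log2 scale. All 100 higher and all 100 lower ones were recovered with 0 false ones, and 3 of 100 unshifted lists fell outside the percentile bounds. The planted change lay above the 2-fold cut, and the simulated noise need not match the spread of the real arrays. The recovery thus checks the steps and gives no rate of false genes among the 2-fold counts. Bounds at the central 95% leave some unshifted lists outside by construction, so their number says nothing about lists of genes that vary together. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1.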

Results

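Gene expression was measured in FaDu cells, an established line from a human hypopharyngeal squamous cell carcinoma, after transient transfection with 100 nM of an siRNA against EpCAM or of a nonspecific control siRNA. EpCAM is a cell surface glycoprotein of epithelia that is abundant in many carcinomas. Total RNA of each condition was labelled with Cy3 and hybridised to 1 one-colour 60-base oligonucleotide array, so each group held 1 array and the comparison had no replicate check. No p-value was computed, and each difference below describes these 2 arrays. Of 43376 gene spots, 66.2% lay well above background on the EpCAM siRNA array and 67.5% on the control siRNA array, and the median spot intensities were 142.3 and 122.4. The errors given are technical: the scanner software's error of the difference was about 0.20 on the log2 scale for bright probes, and the median SD between replicate spots was 0.046 over 212 probes with several spots. The number of arrays limits the precision, since neither error covers the spread between cultures.

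The first question was whether the targeted transcript was lower in the cells that received its siRNA. EPCAM, listed on the array under its older name TACSTD1, was 1.78-fold lower in the EpCAM siRNA array, a log2 difference of -0.83 with an error of 0.20. Its single probe lies at 47525545 to 47525604 on chromosome 2 of hg17, the build of the array's annotation, and read 20933 intensity units against 33078 in the control siRNA array. EPCAM was among the 0.66% of measured genes with the lowest differences. That share was 0.21% without background subtraction and 2.04% with no dim probe filter. The EPCAM difference ranged from -0.89 to -0.63 over 14 other settings. Those that only select probes, spots or rows left it unchanged, since its single probe passes them all.

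Cyclin D1, the G1 cyclin that activates CDK4 and CDK6, was among the genes always reported. CCND1 was 1.23-fold lower in the EpCAM siRNA array, with a log2 difference of -0.30 and an error of 0.20 over 3 probes. Over the other settings it ranged from -0.35 to -0.10, the smallest being that of spike-in scaling, where all genes had a median of 0.21. The probes at 69177414 to 69177473, 69176451 to 69176510 and 69167820 to 69167879 on chromosome 11 gave -0.28, -0.29 and -0.34. Across the 8 spots of the first probe that carried no outlier flag the SD of the difference was 0.058. The other G1/S cyclins did not share this direction throughout. CCND2 had a log2 difference of -0.16 and CCND3 of -0.01, CCNE1 and CCNE2 of 0.31 and 0.27, and CCNA2 of 0.00. With spike-in scaling CCND2 and CCND3 lay above 0, at 0.037 and 0.18. RB1, the retinoblastoma tumour suppressor that restrains E2F factors, was the member of the G1/S list with the largest difference, 1.78-fold lower, and both of its probes were lower, by log2 differences of -0.89 and -0.78. Of the 20 G1/S cyclins, kinases and E2F-Rb regulators, 13 were below 0, 19 lay within 1.5-fold, and the list median of -0.07 lay at percentile 7.51 of 10000 random lists of the same size matched on mean level.

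The second question was how widely the transcriptomes of the 2 arrays differed. Of 12664 genes measured on both arrays, 160 were at least 2-fold higher and 46 at least 2-fold lower in the EpCAM siRNA array, so 77.7% of these genes were higher. In all, 93.5% of the measured genes lay within 1.5-fold, and the correlation across the 26334 probes detected on both arrays was 0.994 (Pearson's r across probes, which are not independent replicates). Scaled on 8 spike-in control probes, the median of all genes stood at 0.21, and the counts were 268 higher and 28 lower, of which 90.5% were higher. The counts rested largely on dim probes: 117 of the 160 and 30 of the 46 genes had a mean level under 1/8 of the array's 75th percentile. With normexp background correction they were 31 and 14. Its offset of 50 shrinks the log2 differences of dim probes whatever their cause, so this fall does not tell false differences from real ones. Genes measured only by probes in rows 190 to 351 of the array made up 45.6% of the higher and 47.8% of the lower genes, against 21.9% of all measured genes.

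The genes with the largest positive differences included several known from neurons and from the actin cytoskeleton. STMN3, a neuronal stathmin that destabilises microtubules, was 9.7-fold higher in the EpCAM siRNA array, with a log2 difference of 3.28, an error of 0.22 and values from 3.06 to 3.47 over 3 probes. RUNDC3A, a neuronal RUN domain protein, and FBXL16, an F-box protein, were 8.18-fold and 6.39-fold higher. The actin-binding proteins NEXN and TAGLN were 5.96-fold and 4.52-fold higher, each by 2 probes that differed by less than their error. DISP2, of the Dispatched family of membrane proteins, was 6.18-fold higher, and NRG2, a neuregulin ligand of ErbB receptors, was 4.40-fold higher. TMEM198 had the largest difference, 12.1-fold higher with an error of 0.27 on the log2 scale, from 1 dim probe in rows 190 to 351. Dim probes in these rows also gave the 4.92-fold, 4.56-fold, 4.38-fold and 4.11-fold higher values of ROPN1L, MGLL, ZNF606 and ABCG4, and the probes of FBXL16 and NRG2 were dim as well. MGLL encodes monoacylglycerol lipase and ABCG4 a sterol transporter.

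Among the 12 genes with the largest negative differences, 10 were dim and had their probe in rows 190 to 351. The 2 others were INHBB, which encodes the beta B subunit of inhibins and activins, and VAV3, a guanine nucleotide exchange factor. INHBB was 3.08-fold lower in the EpCAM siRNA array, with a log2 difference of -1.62 and an error of 0.20, and VAV3 was 3.37-fold lower, with -1.75 and an error of 0.21. The dim genes were ANKRD19P, IQCN, PCDHGA2 and SLC26A10P at 6.66-fold, 5.29-fold, 5.01-fold and 4.84-fold lower, GUCY1A1 at 4.03-fold, NT5E at 3.50-fold, and LAMC3, CCN5, HRG and FGL1 at 3.40-fold, 3.38-fold, 3.31-fold and 3.23-fold lower. A second NT5E probe, well above background only on the EpCAM siRNA array, read 0.38, and with no filter on dim probes the NT5E log2 difference was -0.27. With normexp the log2 differences of 10 of the 12 lower genes and of 7 of the 12 higher genes were smaller by over 1.5 times. These were the dim genes, whose differences the normexp offset shrinks whatever their cause, so it cannot decide whether they are real. NT5E encodes the ecto-nucleotidase CD73 and GUCY1A1 a subunit of soluble guanylate cyclase.

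**Figure D1:**
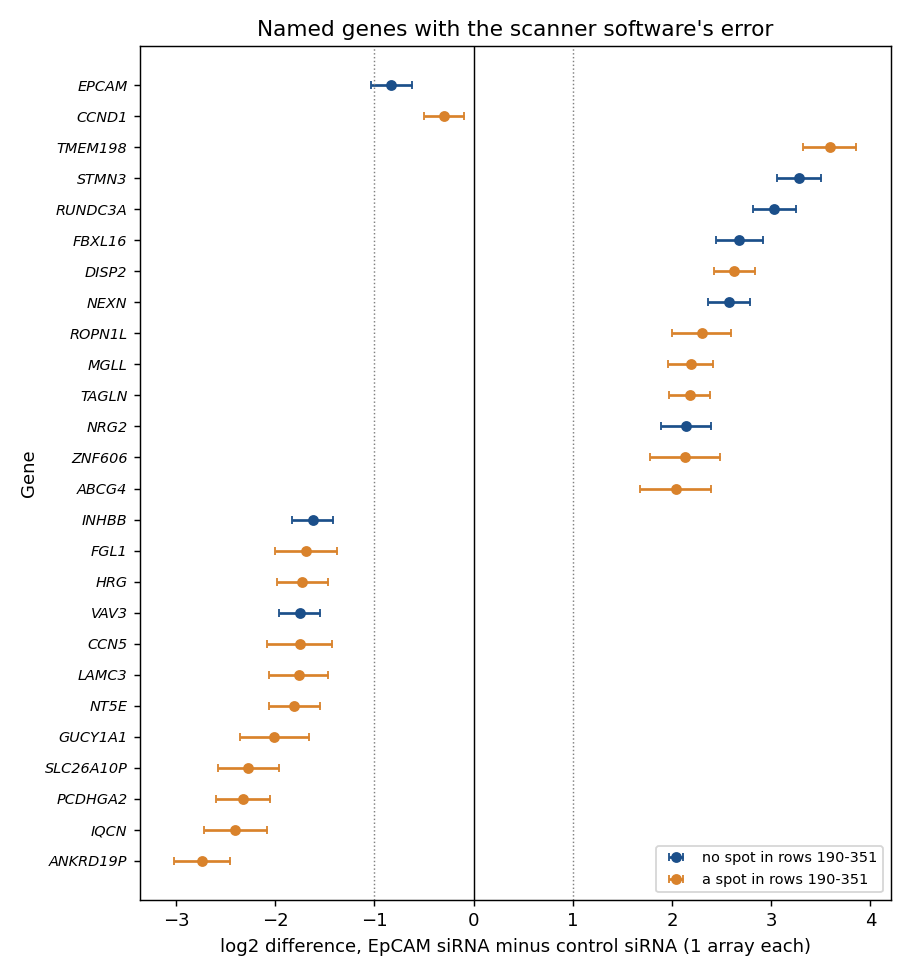
Log2 difference between the EpCAM siRNA array and the control siRNA array (x axis) for EPCAM, CCND1 and the 12 named genes with the largest difference in each direction (y axis); bars are the scanner software's error of the difference, 1 array stands behind each group, and colour marks genes with a spot in rows 190 to 351 of the array. EPCAM lies at -0.83, the higher genes lie between 2.04 and 3.59, and the lower genes between -2.74 and -1.62.

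Genes well above background on only 1 array have a bound in place of a fold, taken against the higher of the dim probe's own signal and the lowest signal well above background on that array. There were 187 such genes seen only in the EpCAM siRNA array, 87 of them with a bound of at least 2-fold, and 353 seen only in the control siRNA array, 74 of them with such a bound. The lowest level well above background was -6.16 on the EpCAM siRNA array and -6.47 on the control siRNA array. The counts of 187 and 353 thus rest on unlike floors and do not show that more genes were lost with EpCAM siRNA. The largest bounds were at least 13.5-fold higher for DMXL2, 12.3-fold for SHBG, 12.2-fold for TMEM119 and 10.8-fold for RHCE. In the other direction they were at least 14.02-fold lower for CALN1, 13.9-fold for CLSTN2, 8.88-fold for ADGRF5 and 8.79-fold for PPEF1. CALN1 rests on 1 of its 2 probes and ADGRF5 on 1 of its 3, the others being detected on neither array. The probes of SHBG, TMEM119, ADGRF5 and PPEF1 lie in rows 190 to 351. Most of the genes with a higher bound of at least 2-fold also rest on a probe with a spot in these rows. So do most of the largest lower bounds, while 31.1% of the spots well above background on both arrays lie there. The limit of dim spots in these rows thus holds for the bounds too.

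Genes of cholesterol synthesis and uptake were lower together in the EpCAM siRNA array. Their median log2 difference was -0.33, lower than that of each of 10000 random lists matched on level, and 24 of 25 measured members were below 0, 15 of them by more than the error. MSMO1, INSIG1, HMGCS1, FDFT1 and SREBF2 had log2 differences of -0.67, -0.64, -0.53, -0.49 and -0.47. HMGCS1 and FDFT1 are enzymes of the mevalonate and squalene steps, and SREBF2 is the transcription factor that drives the pathway. NRF2 targets, genes of the antioxidant response, were also lower, with a median of -0.24 that was below all 10000 random lists and 20 of 22 members below 0. AKR1B10, ABCC3 and UGDH were lower at -0.82, -0.51 and -0.44, and TXNRD1 at -0.41, while HMOX1, which encodes heme oxygenase 1, was higher at 0.80. The genes of MYC-induced ribosome biogenesis and nucleotide synthesis had a median of -0.18 at percentile 0.01, with 24 of 25 below 0 and 7 lower by more than the error. RRP9, RRP12, PAICS, GART, PPAT and NOLC1 gave -0.34, -0.33, -0.31, -0.25, -0.25 and -0.24. With spike-in scaling the medians of these lists were -0.13 for cholesterol, -0.042 for NRF2 and 0.02 for MYC, below the 0.21 of all genes.

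Interferon response genes were lower as a group, with a median of -0.23 that was below all 10000 random lists and 24 of 33 members below 0, 18 of them by more than the error. With spike-in scaling the interferon median was -0.037, against 0.21 for all genes. The chemokine gene CCL5 was at -1.08 with an error of 0.36, from 1 dim probe, and ranged from -1.16 to -0.48 over the other settings. It was followed by HERC5, IFIT3, IRF1 and SAMD9 at -0.59, -0.58, -0.54 and -0.48, whereas IFI6 was higher at 0.49. NF-kB and inflammatory cytokine genes had a median of -0.10 at percentile 2.14, and 16 of 22 members were below 0. IL6 and LIF, both cytokines of the interleukin 6 family, gave -0.68 and -0.59, CXCL2, CXCL1 and NFKB1 gave -0.35, -0.34 and -0.34, and the adhesion molecule gene ICAM1 gave 0.32. This list lay within the central 95% of the random lists in 4 of 16 other settings, and its median was 0.09 with spike-in scaling, against 0.21 for all genes. The median of antigen presentation genes, -0.11, lay inside the range of the random lists at percentile 3.73 and below it in 4 of 16 other settings, with 11 of 14 members below 0. PSMB10, ERAP1, TAP2 and PSMB8 were at -0.51, -0.48, -0.40 and -0.35.

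The joint list of EGFR ligands and immediate early genes was higher in the EpCAM siRNA array, with a median of 0.17 at percentile 99.8, and 20 of 28 members above 0, 13 of them by more than the error. The members with the largest values were feedback regulators and targets of the ERK pathway: the phosphatase genes DUSP6 and DUSP1 at 1.16 and 1.03, SPRY4 at 0.98 and ETV5 at 0.91. BTC, the only EGFR ligand among the members of this list named here, was lower at -0.60, from 1 dim probe in rows 190 to 351. The 2 probes of SPRED2 disagreed, with -1.71 from a dim probe in rows 190 to 351 and 0.52 from the brighter probe. This list stayed above the central 95% of the random lists in all 16 other settings, some of which, such as spike-in scaling, could not change a percentile. Wnt/beta-catenin targets had a median of 0.22 at percentile 99.9, with 12 of 19 above 0. AXIN2, SP5, PPARD, TCF7 and BMP4 were at 0.70, 0.58, 0.49, 0.40 and 0.39, and CCN5 was at -1.76. The brightest probe of SP5 read -0.30 and its 2 dimmer probes 0.94 and 1.09, and over the other settings the values of AXIN2 and BMP4 reached down to -0.079 and -0.014. With the brightest probe of each gene the median of the Wnt list was -0.03, at percentile 18.4, and in 6 of 16 other settings the list lay within the central 95%. TGF-beta targets did not stand apart, with a median of 0.03 at percentile 60.9, because members lay on both sides: CCN2 and COL1A1 were higher at 1.79 and 0.999, and TGFBI was lower at -0.98. COL1A1 rests on 1 dim probe with at least 1 spot in rows 190 to 351, and it ranged from 0.38 to 1.20 over the other settings.

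Genes of epithelial cells differed by group. Epithelial junction genes had a median of -0.11 at percentile 0.58, with 20 of 32 members below 0, 9 of them by more than the error. TJP3, CLDN4, DSG2, CLDN1 and CLDN7 gave -0.72, -0.58, -0.51, -0.44 and -0.40, and PARD6B, a polarity gene, gave 0.34. Claudin 7 is a binding partner of EpCAM. The percentile of this list was within the random range in 2 of 16 other settings. These were brighter probes only, at percentile 8.9, and without rows 190 to 351, at percentile 3.95. With spike-in scaling the median of the junction list was 0.09. Basal keratinocyte genes had a median of 0.13 at percentile 99.8, and 12 of 18 members were above 0. COL17A1 and KRT17 were at 0.87 and 0.71, DST and ITGA6 at 0.42 and 0.34, and NGFR at -0.54. Without rows 190 to 351 the median of the basal list was 0.06, at percentile 91.6. Epithelial regulators had a median of -0.07 at percentile 10.4, with TMPRSS4, MAL2, GRHL3 and ELF3 at -0.78, -0.77, -0.65 and -0.57. Squamous differentiation genes had a median of -0.08 at percentile 6.59 and lay below the random range in 6 of 16 other settings. Of its members 14 of 17 were below 0, among them KLK10 at -0.78, LCN2 and KLK5 at -0.61 each, and RHCG at -0.48. The mesenchymal list had a median of -0.05 at percentile 16.4 and a mean of 0.22, the mean being set by TAGLN at 2.18, FN1 at 1.39, SNAI2 at 0.78 and TNC at 0.54. Over the other settings SNAI2 ranged from 0.33 to 0.98 and TNC from 0.28 to 0.74. The values of TJP3, GRHL3, RHCG and TNC each came from 1 dim probe in rows 190 to 351.

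Proliferation genes differed little between the arrays. All 34 DNA replication genes lay within 1.5-fold, with a median of -0.08 at percentile 5.34 and 24 below 0. GINS1 was at 0.39, and MCM3, CDC45 and TYMS were at -0.38, -0.35 and -0.33. All 36 mitosis genes also lay within 1.5-fold. Their median of 0.04 was at percentile 98.0, with BUB1 and NDC80 at 0.30 and 0.29, KIF23, CENPE and HMMR at -0.23, -0.18 and -0.17, and CENPA at 0.17, and 2 members were higher and 1 lower by more than the error. The percentile of the mitosis list was within the random range in 9 of 16 other settings, and its median was -0.01 in the authors' series table. The 8 CDK inhibitors had a median of 0.15 at percentile 95.5, with CDKN2D and CDKN2C at 0.40 each, CDKN1C at 0.30 and CDKN1A at -0.41. The 65 ribosomal protein genes had a median of -0.07 at percentile 37.1, with RPS24, RPS4X, RPL13A and RPL3 at -0.32, -0.24, -0.21 and -0.20. Of these genes 61 were below 0, and 95% of the random lists matched on their level had medians from -0.096 to -0.028. A count of members below 0 in a list of bright genes, such as the MYC list, thus partly follows level.

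**Figure D2:**
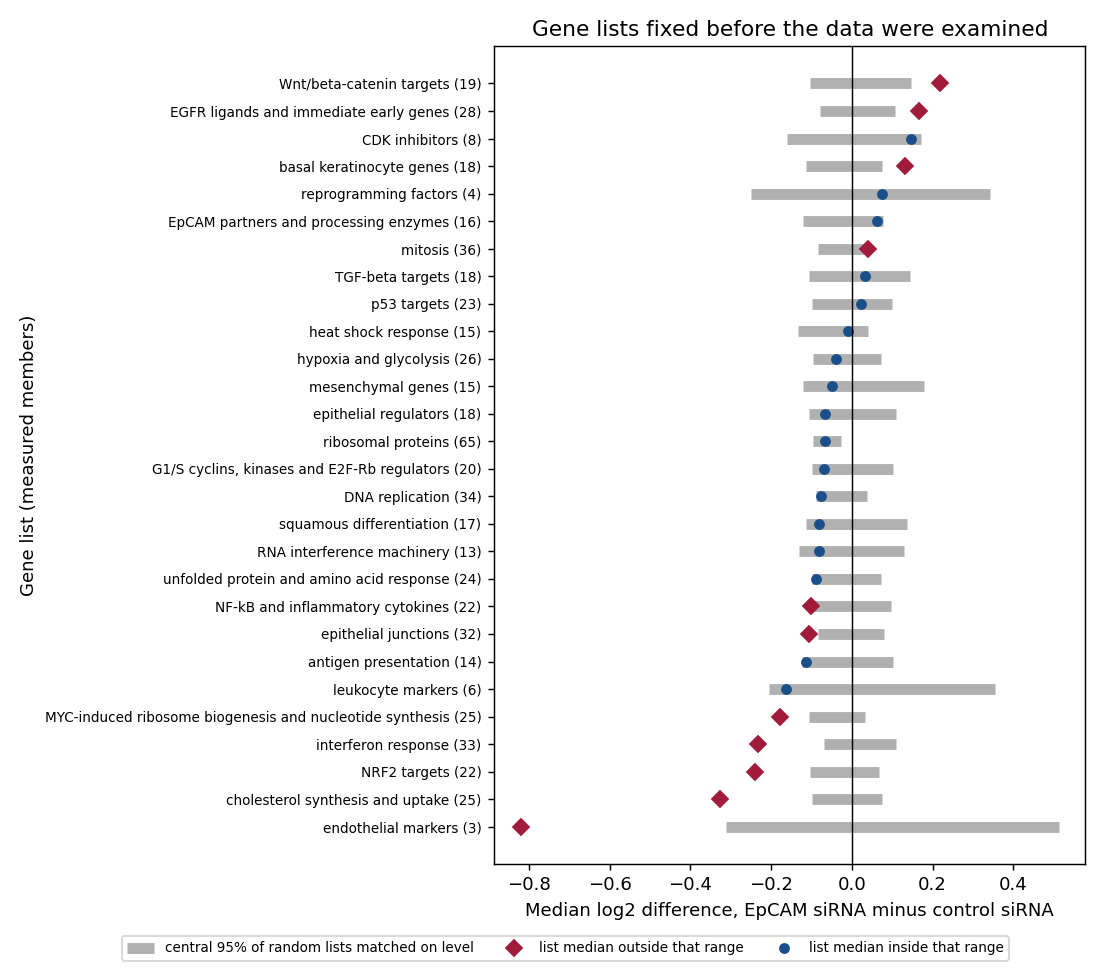
Median log2 difference (x axis) of each gene list fixed before the data were examined (y axis, measured members in parentheses), with the central 95% of the medians of 10000 random lists matched on mean level as grey bars. Cholesterol, NRF2, interferon and MYC lists lie left of their bars at -0.33, -0.24, -0.23 and -0.18, and the Wnt, EGFR and basal keratinocyte lists lie right of them at 0.22, 0.17 and 0.13.

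The p53, heat shock and hypoxia lists lay inside the range of random lists in all 16 other settings as well, some of which could not change a percentile. The p53 targets had a median of 0.02 at percentile 67.8, with GDF15 at -0.76, BTG2 at 0.72, and CDKN1A and PLK3 at -0.41 and 0.41. Genes of the unfolded protein and amino acid response had a median of -0.09 at percentile 3.61, below the random range in 5 of 16 other settings, with CEBPB, CHAC1 and ATF5 at -0.53, -0.49 and -0.47 and PPP1R15A at 0.40. Heat shock genes had a median of -0.01 at percentile 82.5, with HSPA4L at 0.62, HSPD1 at -0.33, HSPA6 at 0.31 and DNAJA1 at -0.23. Genes of hypoxia and glycolysis had a median of -0.04 at percentile 27.4, with BNIP3 at 0.75, EGLN3 at -0.74, P4HA2 at 0.63 and ANKRD37 at 0.51. Among the 16 measured EpCAM partners and processing enzymes, EPCAM itself included, the median was 0.06 at percentile 95.3, and 10 members were above 0. By more than the error 4 members were higher and 5 lower, with EPCAM, APH1A and CLDN7 at -0.83, -0.46 and -0.40. The reprogramming factors SOX2, POU5F1, MYC and KLF4 gave 0.21, 0.14, -0.11 and 0.01, with a median of 0.07 at percentile 63.0. The RNA interference machinery had a median of -0.08 at percentile 9.13, with TNRC6C and AGO2 at 0.79 and 0.72, DICER1 at -0.36 and AGO3 at -0.16.

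Marker genes of cell types other than the carcinoma cells were mostly not above background. Of 10 fibroblast markers 2 were measured, COL1A1 at 0.999 and COL6A3 at -0.30, each from 1 dim probe with at least 1 spot in rows 190 to 351. Of 12 leukocyte markers 6 were measured, with a median of -0.16 at percentile 4.82 and CD68, ITGAM, CD2 and CD14 at -0.60, -0.43, 0.22 and -0.18. Of 8 endothelial markers 3 were measured, with a median of -0.82 that was below all 10000 random lists: CDH5 at -1.25, VWF at -0.82 and ERG at -0.10, the CDH5 probe and 5 of the 10 VWF spots lying in rows 190 to 351. The VWF spots outside these rows gave -0.75. With no filter on dim probes the endothelial median was 0.23, at percentile 35.0.

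Spots in rows 190 to 351 differed between the arrays more often than other spots when they were dim. Of 2499 dim spots inside these rows, 6.64% were at least 2-fold apart, against 2.32% of 5207 dim spots outside them. Of brighter spots, 0.67% inside and 0.65% outside were at least 2-fold apart.

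**Figure D3:**
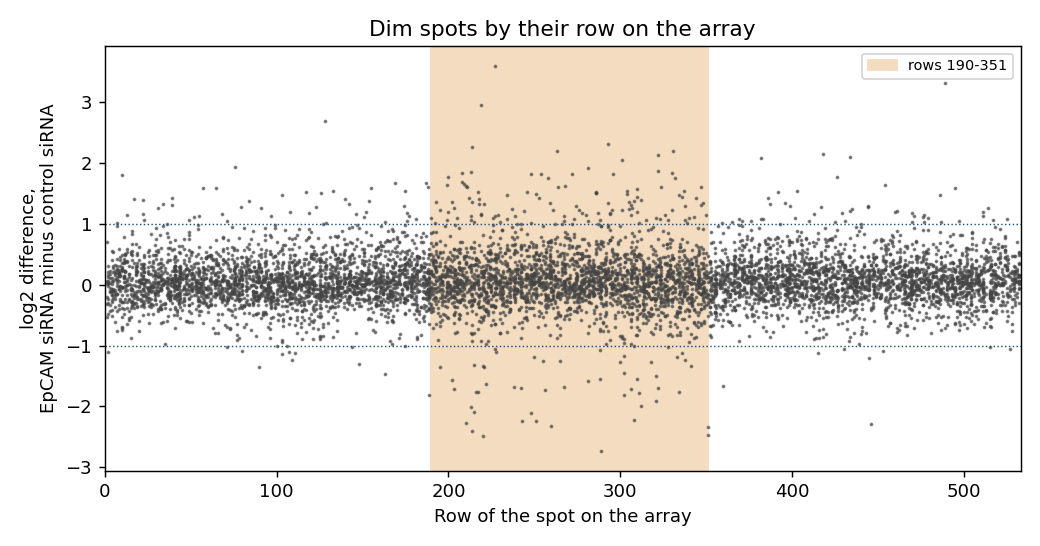
Log2 difference between the EpCAM siRNA array and the control siRNA array (y axis) of each dim spot, with a mean level under 1/8 of the array's 75th percentile, against its row on the array (x axis); dotted lines mark 2-fold and shading marks rows 190 to 351. Points beyond the dotted lines are denser in the shaded rows, 6.64% of spots against 2.32% elsewhere.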

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

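The thresholds for unnamed probes, the limits of the rows and all tests of array position were chosen after the results were seen. Among probes without a current gene symbol, which entered no gene result, 4 stood well above the control siRNA array. PRO1848 was saturated in the EpCAM siRNA array and not well above background in the control siRNA array, with a bound of 11.93 on the log2 scale, or at least 3891-fold higher. The PRO1848 value rests on 1 spot per array, so no replicate spot checks it. ENST00000358378 was also seen only in the EpCAM siRNA array, with a bound of 3.34, and its probe lies in row 295. AK092450 was detected on both arrays with a log2 difference of 2.94 and an error of 0.27, and its probe lies in row 219. ENST00000304389 was detected on both arrays with a log2 difference of 2.07 and an error of 0.24. They are 4 of 36 unnamed probes that were at least 4-fold higher, bounds included, and 27 were at least 4-fold lower. Of those detected on both arrays, 2 were higher and 5 lower by that size.

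A pattern of the arrays themselves bears on many dim genes: differences of at least 2-fold crowd in rows 190 to 351, with sharp edges, in both directions. Dimmer probes in these rows do not account for it, since the levels of the dim spots alone would give a share at least 2-fold apart that is 0.980 times that of other rows, with a bootstrap SE of 0.013. Whether the position of the spots produced the excess may be asked of second probes that lie outside the rows: for 31 dim probes inside the rows they had a median of 0.41 in the direction of the first probe, against 0.19 for 18 dim probes outside, a gap of 0.23 with a bootstrap SE of 0.26. Replicate-spotted dim probes were examined first, 30 probes with 270 spots, 84 of them inside the rows. In any row 0 of these spots lay at least 2-fold from their probe's median, and the SD from that median was 0.21 inside the rows and 0.17 outside. Scatter by position large enough to make 6.64% of dim spots 2-fold apart was thus not seen in these 30 probes. They are few beside the 2499 dim spots in the rows, so they do not settle the matter for the genes of the excess. The second probes were added because no replicate spot was 2-fold off. The need for a gap of at least 1 SE was set only after both medians had been seen. Without it the higher median of second probes for probes inside the rows would have counted against position. The gap is smaller than its error, so by the second probes position and a real difference between the RNAs cannot be told apart for these genes. A biological explanation was not tested.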

How the results depend on the processing

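Leaving out rows 190 to 351 and counting only brighter genes were chosen after seeing the data. The EPCAM difference stayed below 0 in 14 settings. Settings that only select probes, spots or rows could not move it, because EPCAM has 1 bright probe outside rows 190 to 351. None of the 31 named genes at least 2-fold apart reversed in 391 values, though 55 moved by more than the error, mostly under other background treatments. Most of these genes were measured by 1 probe, so taking the brightest or the median probe could not change their values. Genes higher and lower numbered 557 and 269 at 1.5-fold, 36 and 13 at 3-fold, 31 and 14 with normexp, 37 and 16 without background subtraction, 268 and 28 with spike-in scaling, 486 and 264 with no dim filter, 22 and 10 with brighter probes only, 91 and 25 without rows 190 to 351, and 43 and 16 for genes at 1/8 of the 75th percentile or above. The cholesterol, NRF2, interferon, MYC, EGFR and actin (SRF and YAP) lists lay outside the random range in all settings. Settings that shift each array by 1 constant or leave out saturated probes could not have moved a list into or out of that range. Of the lists inside the range, squamous differentiation lay below it in 6 settings, unfolded protein in 5, antigen presentation in 4, and DNA replication, epithelial regulators, ribosomal proteins and leukocyte markers in 1 each. With spike-in scaling, which moved the median of all genes to 0.21, list medians were 0.24 for mitosis, 0.019 for MYC, 0.41 for Wnt, 0.091 for epithelial junctions, 0.33 for basal keratinocytes, -0.037 for interferon, 0.095 for NF-kB, -0.13 for cholesterol, -0.042 for NRF2, 0.36 for EGFR, 0.41 for REST and 0.45 for actin; the sign turned for MYC, junctions and NF-kB, by the shift of all genes. In the authors' series table they were -0.0071 for mitosis, which turned sign, -0.23 for MYC, -0.15 for junctions, 0.085 for basal keratinocytes, -0.28 for interferon, -0.37 for cholesterol, -0.29 for NRF2 and 0.20 for actin; that table also moved the median of all genes, to -0.04. Median scaling gave 0.0075 for mitosis, and quantile and loess normalization gave -0.13 each for MYC. Wnt was 0.0018 with normexp, 0.090 without background subtraction, 0.057 with no dim filter, 0.090 as a mean, and reversed to -0.031 with brighter probes only and with the brightest probe. Endothelial markers were -0.46 with normexp, -0.35 without background subtraction and reversed to 0.23 with no dim filter. REST targets reversed to -0.043 with normexp and were 0.051 without background subtraction, 0.30 with no dim filter and 0.34 with brighter probes only. The EGFR median was 0.23 with brighter probes only, with the brightest probe and without rows 190 to 351, the basal median was 0.062 without those rows, and the actin mean was 0.31. Beyond scaling shifts the cause was not tested. Dim probes limit the counts: their signals lie near background, and the counts were smaller with normexp and without background subtraction. Both settings shrink the log2 differences of dim probes whatever their cause, so the smaller counts do not show which differences are false. The search of seed sites in untranslated regions was not run.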

Other observations

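The lists of actin and REST target genes and all tests on the REST list were chosen after the results were seen, as were the GC tests of the seed sites and the use of a 6-base site; the other seed tests were set before their results, but the use of an SE and of sites of the same GC content in judging them was added afterwards. Target genes of SRF and YAP, which tie the actin cytoskeleton to transcription, were collected without TAGLN, NEXN and CCN2, whose values had prompted the list. They were higher in the EpCAM siRNA array, with a median of 0.25 above that of all 10000 random lists and 24 of 28 members above 0, 17 of them by more than the error. MYL9, TGFB1I1, CALD1, ACTG2 and LIMA1 were at 1.15, 1.11, 0.84, 0.70 and 0.62. CR601567, an unnamed probe with 1 spot per array, was saturated in the control siRNA array and at least 47.4-fold lower in the EpCAM siRNA array.

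Several of the genes with the largest positive differences are neuronal, and a list of 62 neuronal genes repressed by REST, a transcription factor that silences neuronal genes outside the nervous system, was drawn up without them. Of 31 measured members 21 were above 0, with a median of 0.22 at percentile 99.4, and SCN8A and MAPK8IP2 were at 1.41 and 1.13. The 9 members with brighter probes had a median of 0.34, above the random range, which reached 0.15. They are not dim by selection, so this shows only that the difference was not confined to dim members. Normexp, which changes bright probes little, gave 0.32. This test took the place of one without rows 190 to 351, where the list's median was 0.19 at percentile 98.1, after both values were known. The 22 members with dimmer probes only did not stand apart to begin with, at a median of 0.19 and percentile 87.0, so their median of -0.052 after normexp decides nothing, a limit set after those values were seen. Chance in the choice of the list stays open, because the list lay inside the random range in 4 of 16 settings, with a median of -0.04 at percentile 84.5 after normexp. A lower REST transcript could be a biological source, but the REST probes disagree. The brighter probe read -0.63 with an error of 0.20, and the dim probe 0.12, within its error of 0.22.

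Each siRNA can also act on other transcripts through its seed, so the arrays were searched for probes holding the matching 7-base sites. For the passenger strand of the EpCAM siRNA, taken to be the strand that the labels print, 92 probes with CACTGGC had a median of -0.072 with an SE of 0.028, at percentile 1.16 among sites of similar frequency and 1.47 among sites of the same GC content, past the lower limits of -0.060 and -0.066 by less than the SE, so an effect of this site and its GC content both stay open at this length, though without the trend with probe GC content the median was -0.084, at percentile 1.09. For the shorter 6-base part of the site, held by 339 probes with a median of -0.091, an SE of 0.017 and percentile 0.076, GC content does not account for the value, which lay beyond the limit of -0.034 for sites of the same GC content and was -0.106 without the GC trend, where the limit was -0.046. The other 6-base sites did not pass their limits, the EpCAM guide's lying at percentile 6.46 and the control guide's and passenger's at 94.7 and 55.3. The guide's site lay at percentile 7.83, short of its limit by less than its SE, which leaves it open too; the control siRNA's guide and passenger sites, the latter held by 9 probes, lay at percentiles 81.0 and 1.27, where an effect would lie at the upper end. With 8 sites tested, 4 of each length, chance may also give such a value, and with 1 siRNA per arm an effect of EpCAM loss and one of the siRNA sequence remain untested against each other.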
